A study of Mus musculus with 59 samples.

How the data were processed

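RNA from the livers of male C57BL/6 mice, 6 weeks old at the start and given 2 weeks to acclimate, was hybridised to 1-colour Affymetrix mouse expression arrays, 1 array per sample. The 59 samples fall into 12 groups of 5 arrays, except that the group given 100 ppb arsenite in water on the AIN-76A diet has 4. The labels call the samples of a group biological replicates. The p-values measure the spread between these samples, and the number of arrays limits the precision.

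The values used here are log2 expression values per probe set, deposited by the authors after background correction, normalization and summarisation with RMA, per the submitters' processing notes. The RMA software, its version and its settings are not given in the sources used here. The deposited values run from 1.17 to 14.2, and the array medians lie between 2.42 and 2.59. The upper quartiles of the arrays lie between 3.74 and 4.31, so the arrays share similar but not identical distributions. No scanner files were used here, no value was filtered and no further normalization was applied before the tests. RMA pulls probe sets near the background together, so a fold change of a dim gene can be understated. No pair of arrays was a duplicate, since the closest pair had a correlation of 0.994 across probe sets and differed with an SD of 0.22 on the log2 scale.

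Of 45101 probe sets, 64 controls were left out and 45037 were tested. Gene symbols came from the platform annotation, in which 34958 probe sets have 1 symbol and 932 have several. Of the probe sets tested, 10092 have no single symbol and were not named. The gene identifiers of 34754 of the probe sets with 1 symbol were found in the RefSeq table for the GRCm38.p6 mouse assembly, and no symbol needed an update. Each of 18193 genes was represented by the probe set with the highest mean over all 59 arrays, and 9010 genes have more than 1 probe set. Among the named genes, probe sets disagreed in sign for Ighm, Arntl, Acacb, Hsd17b6, Elovl6, Arhgap26, Lpin2, Atp1b1, Zkscan6 and Tef. No probe set of these genes was called in the opposite direction.

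Group means were fitted with limma 3.58.1 in R 4.3.3, separately for the 39 arrays of the 8 groups exposed for 5 weeks and for the 20 arrays of the 4 groups taken 8 hours after an injection. Every contrast was tested with moderated statistics, and p-values were adjusted over all probe sets of a contrast by the Benjamini-Hochberg method with a threshold of 0.05. The contrasts were the diets in control mice and averaged over exposures, each arsenite exposure against the control of its diet, the diet by exposure interactions, food against water at 10 ppb, 100 against 10 ppb in water, each injection against saline, arsenite on top of dexamethasone, dexamethasone on top of arsenite, and their interaction. Diet was also tested within each exposure level, and the probe sets called with 1 sign at all 4 levels were counted. In each contrast, chance alone gives 2252 probe sets at an unadjusted p under 0.05.

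A set of 34 gene lists with 572 entries, of which 512 were measured, was written from textbook knowledge. The 20 pathway lists cover glucocorticoid targets, gluconeogenesis, amino acid breakdown with the urea cycle, cytochrome P450, Nrf2 and glutathione genes, conjugation, arsenic handling, heat shock and metal response, endoplasmic reticulum (ER) stress, lipogenesis, cholesterol synthesis, bile acids, fatty acid oxidation, the circadian clock, the acute phase, inflammatory signalling, interferon response, cell cycle, and male-biased and female-biased genes. The 14 lists of cell types and liver zones cover hepatocytes, Kupffer cells, MHC class II, T and NK cells, B cells, neutrophils, endothelium, stellate cells with fibroblasts, bile duct cells, red cells, pancreas, fat, and pericentral and periportal hepatocytes. Some genes stand in more than 1 list. Lists were tested with camera on 1 probe set per gene, with a preset correlation between genes of 0.01 and with a correlation estimated from the data, and adjusted over the lists of 1 kind within a contrast. An adjusted p of a list is from the preset correlation unless the text says estimated. Counts of members are given adjusted over all probe sets and adjusted over the list alone.

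The groups, the contrasts, the gene lists, the alternatives and the rule for named genes were fixed before the data were examined, except where an addition is named. In the main contrasts the rule takes, among genes past the threshold, the 12 largest rises and 12 largest falls whose groups do not overlap, or, for the averaged diet contrast, those with 1 sign at all 4 exposure levels. Chance alone separates 5 arrays from 5 in 0.794% of splits and 4 from 5 in 1.59%. Where fewer than 5 genes passed, the 5 genes with the smallest p are named. In the other contrasts the 3 largest rises and falls that passed are named, and for each list up to 4 members with the smallest p. The text names fewer genes than the rule gives, with preference, chosen after the values were seen, for those whose call held when single arrays were left out. Of 258 called values of named genes, 62 lost their call without some single array.

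The alternatives were a filter for the brighter probe sets, 1 probe set per gene, all 59 arrays in 1 fit, only the groups compared, a repeated quantile normalization, a variance trend, the replicate letter of the labels as a block, and leaving out each array in turn. After the data were seen, a block for 12 arrays that lie apart and a fit without them were added, and the lists were also run under each of these settings. For each contrast, 100 splits of the samples were drawn to count how often other groupings give as many calls.

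The scripts were tested on simulated data in which, of 45037 probe sets, 66 changed by 0.5, 67 by 1 and 67 by 2 on the log2 scale. The noise was normal and independent, with 1 SD per probe set in all groups. Real probe sets deviate together and the real groups differ in spread, so the shares and false calls need not hold for them. In the contrast of diets in controls, 50% of changes of 0.5 on the log2 scale were recovered, 88.1% of changes of 1 and 94% of changes of 2, with 7 false calls. The averaged diet contrast recovered 84.8%, 100% and 100%, with 10 false calls. For 100 ppb arsenite in water on AIN-76A, the shares were 39.4%, 85.1% and 100%, with 10 false calls. For the dexamethasone injection they were 45.5%, 86.6% and 100%, with 7 false calls. For the interaction of dexamethasone and arsenite they were 7.6%, 64.2% and 91%, with 6 false calls. Among simulated lists of 20 independent genes out of 18193, the list shifted by 0.5 was called and 0 of 49 unshifted lists were. Members of the real lists can be correlated, so this does not give their rate of false calls.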

Results

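Liver gene expression was measured on 59 arrays from mice on 2 diets, with and without inorganic arsenic given as sodium arsenite. AIN-76A is a diet made from purified ingredients, and LRD-5001 is a standard rodent chow. On each diet, mice were exposed for 5 weeks to no added arsenite, to 10 or 100 ppb in drinking water, or to 10 ppb in food. In a separate experiment on AIN-76A, livers were taken 8 hours after an intraperitoneal injection of saline, dexamethasone at 1 mg/kg, arsenite at 1 mg/kg, or both. Dexamethasone is a synthetic glucocorticoid, and the design sets arsenite beside diet, route of intake and this hormone. Each group held 5 arrays, except for 4 in the group given 100 ppb in water on AIN-76A. Differences below are on the log2 scale with their standard error (SE), and each rests on these group sizes. The SE uses 1 spread per probe set from all arrays of the experiment, not from the groups compared alone. It is too small where those groups vary more, and too large where they vary less.

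**Figure D1:**
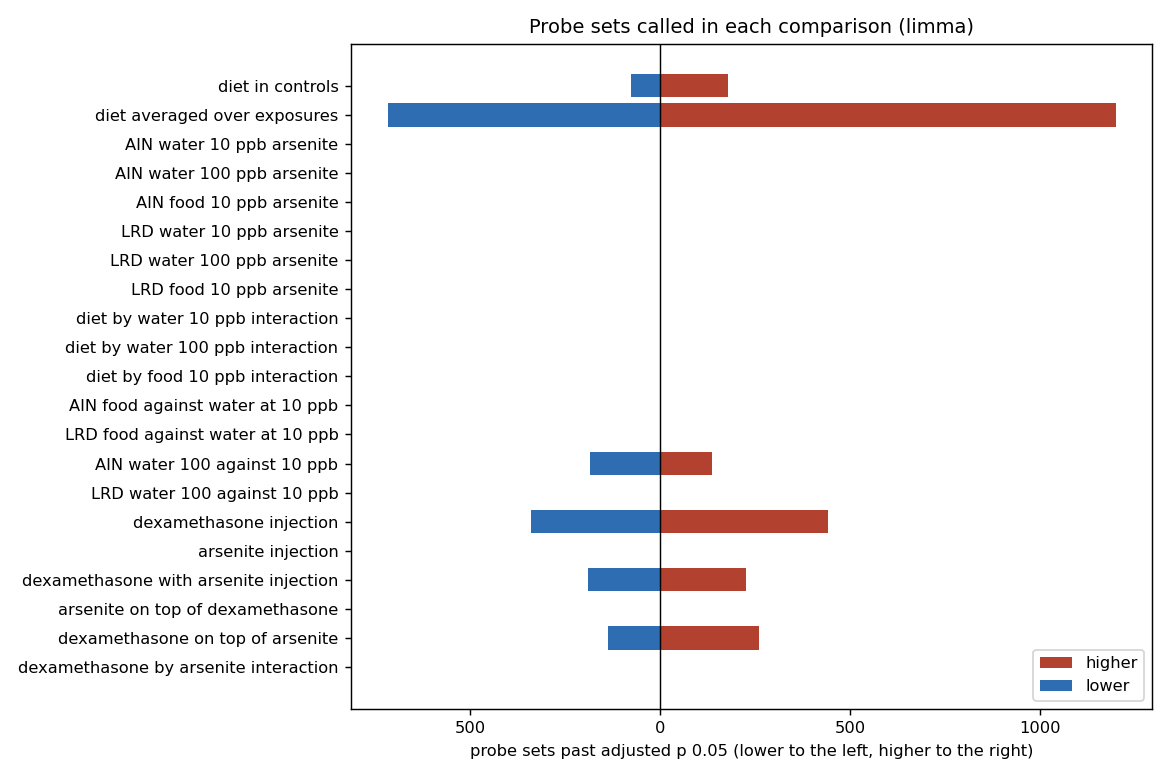
Number of probe sets with an adjusted p under 0.05 in each contrast, higher and lower shown apart. Diet averaged over exposures gave 1919 calls and dexamethasone 782, while arsenite against its own control gave 4 at most.

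In every group, 1 array lay apart on the first component of the deviations from the group means, which held 31.2% of that variance. These 12 arrays had an upper quartile lower by 0.267 on average than the other arrays of their groups (mean difference -0.267, SD 0.081 over groups, permutation p = 1e-05, the smallest these permutations can give). The component was built from brighter probe sets and signed so that a low score goes with a low upper quartile. The 12 arrays are its lowest scores, so this p partly restates how they were chosen. Counts that move with these arrays are given with them as a block and without them, both settings chosen after the data were seen.

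**Figure D2:**
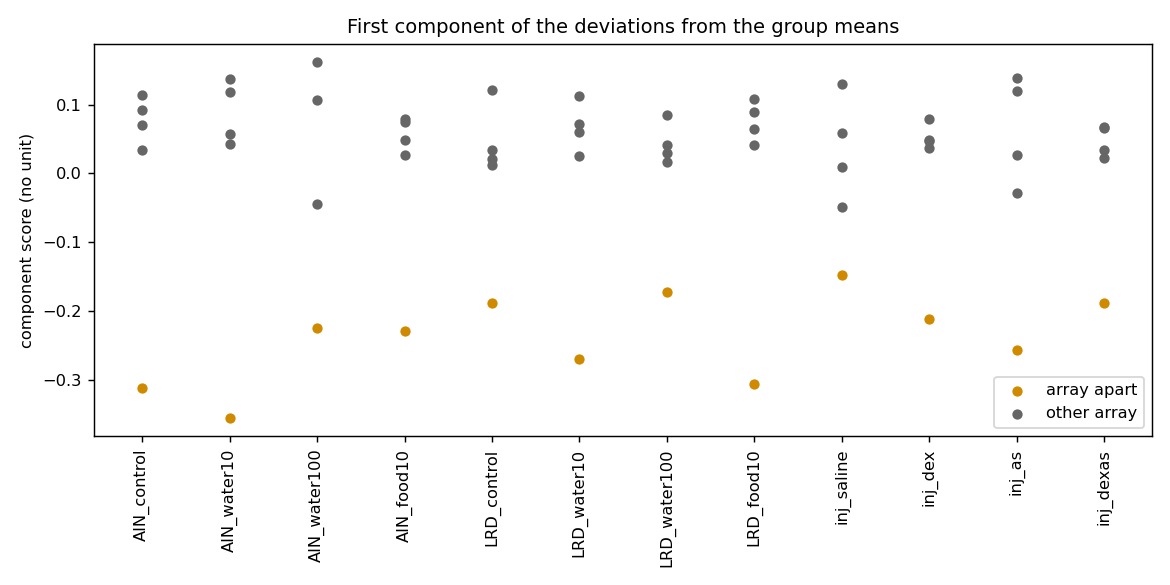
Score of each array on the first component of the deviations from the group means (no unit), by group, with the 12 arrays that lie apart in orange. The highest score among them is -0.148 and the lowest among the other 47 arrays is -0.049.

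In control mice, several genes of detoxification were higher on LRD-5001 than on AIN-76A, and the lipid genes Fabp5 and Apoa4 were lower. Gsta2, a glutathione S-transferase, had a mean of 8.98 ± 0.61 (SD, n = 5) on LRD-5001 and 4.04 ± 1.06 (SD, n = 5) on AIN-76A, a difference of 4.94 (SE 0.52, adjusted p = 2.87e-07). Clec2h, a C-type lectin-like gene, rose from 3.48 ± 0.59 to 7.11 ± 0.30 (SD, n = 5 each). Cyp26a1, which breaks down retinoic acid, rose by 3.37 (SE 0.52), the glutathione transferases Gsta4 by 2.85 (SE 0.47) and Gstt2 by 2.62 (SE 0.32), the efflux transporter Abcc3 by 2.84 (SE 0.32), and the uridine phosphorylase Upp2 by 2.75 (SE 0.46). Tff3, a trefoil peptide, fell from 9.42 ± 1.24 to 5.48 ± 0.60 (SD, n = 5 each), and the scavenger receptor Scara5 fell from 7.39 ± 0.94 to 4.37 ± 0.90 (SD, n = 5 each). Fabp5, a fatty acid binding protein, fell by 2.98 (SE 0.39), and the apolipoprotein gene Apoa4 fell by 2.73 (SE 0.27). For each gene of this paragraph, all 5 arrays of 1 diet lay above all 5 of the other. The rule for named genes selects for this, and it held for 1.85% of all probe sets. In all, limma called 256 probe sets, 180 higher and 76 lower on LRD-5001, against 3249 at an unadjusted p under 0.05. The count was 170 without LRD-5001 control replicate D, 165 without its replicate F, 157 with all 59 arrays in 1 fit, and 165 with only the groups compared. It was 434 with the arrays apart as a block and 272 without them.

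Among the lists, 7 of 24 cytochrome P450 genes rose in LRD-5001 controls, 0 fell and 17 did not pass (13 rose adjusted over the list alone). They included Cyp2c55 (2.18, SE 0.34), Cyp2c37 (2.16, SE 0.40) and Cyp2c54 (2.01, SE 0.40), and the list was higher with an adjusted p of 5.71e-17 (adjusted p = 0.00126 with an estimated correlation). Of 24 Nrf2 and glutathione genes, 7 rose and 17 did not pass (12 rose and 1 fell adjusted over the list alone), with Gsta2, Gstt2, Gstt3 (1.78, SE 0.27) and the epoxide hydrolase Ephx1 (1.67, SE 0.24) having the smallest p (adjusted p = 1.18e-16 for the list; adjusted p = 0.00543 with an estimated correlation). Of 18 conjugation genes, 4 rose and 14 did not pass (11 rose adjusted over the list alone), among them Ugdh, which makes UDP-glucuronic acid (1.15, SE 0.20; adjusted p = 0.012 for the list with an estimated correlation). In the arsenic handling list, 2 of 16 genes rose (3 adjusted over the list alone), Abcc3 and the efflux transporter Abcc2 (0.62, SE 0.12), and the list median was 0.064 (adjusted p = 0.0197 with an estimated correlation). The arsenic methyltransferase As3mt is a member of this list and was not among its called genes. The acute phase, bile acid, fatty acid oxidation, interferon response, Kupffer cell, MHC class II and pericentral lists were called with the preset correlation only.

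Lipid genes moved in both directions. Of 20 genes of cholesterol synthesis and uptake, 6 rose in LRD-5001 controls and 14 did not pass (10 rose adjusted over the list alone). They included Hmgcs1, which makes HMG-CoA for the mevalonate pathway (1.17, SE 0.17), and the methylsterol oxidase Msmo1 (1.44, SE 0.22), with adjusted p = 0.0197 for the list with an estimated correlation. Of 22 lipogenesis genes, 6 fell and 16 did not pass (13 fell adjusted over the list alone), among them the fructose kinase Khk (-0.93, SE 0.18), the fatty acid elongase Elovl5 (-1.42, SE 0.28) and pyruvate kinase Pklr (-2.12, SE 0.46; adjusted p = 0.0437 for the list with an estimated correlation). Pklr lost its call without AIN-76A control replicate F (adjusted p = 0.0501) and without LRD-5001 control replicates B (adjusted p = 0.0705) and D (adjusted p = 0.0669). In the amino acid and urea cycle list, 1 of 15 genes rose, the tryptophan dioxygenase Tdo2 (0.58, SE 0.12), and 8 rose adjusted over the list alone (adjusted p = 0.00906 for the list with an estimated correlation). The adjusted p of Tdo2 was 0.0582 without AIN-76A control replicate E.

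Clock genes differed between the diets in both directions. Of 18 clock genes, 4 rose, 2 fell and 12 did not pass in LRD-5001 controls (8 rose and 2 fell adjusted over the list alone). The PAR bZIP factors Tef and Dbp rose by 1.64 (SE 0.19) and 3.28 (SE 0.71), whereas the core activator Arntl fell by 1.77 (SE 0.24) and the repressor Nfil3 fell by 1.5 (SE 0.23). Dbp lost its call without AIN-76A control replicate E (adjusted p = 0.0963) and without LRD-5001 control replicate F (adjusted p = 0.0512). The list as a whole had an adjusted p of 0.00452 (adjusted p = 0.0693 with an estimated correlation).

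Averaged over the 4 exposure levels, several detoxification genes were again higher on LRD-5001. Some lipid genes and the acute phase genes Lcn2 and Saa2 were lower. Gsta2 rose by 4.5 (SE 0.27), Clec2h by 3.64 (SE 0.16), Cyp26a1 by 3.21 (SE 0.27), the drug-metabolising Cyp3a11 by 3.0 (SE 0.32) and the carboxylesterase Ces1g by 2.35 (SE 0.26). Apoa4 fell by 3.01 (SE 0.14), Fabp5 by 2.77 (SE 0.20), Ighm, the heavy chain of IgM, by 2.40 (SE 0.28), and Elovl6, another fatty acid elongase, by 1.68 (SE 0.19). The acute phase genes Lcn2 and Saa2 fell by 3.34 (SE 0.74) and 2.64 (SE 0.60). Here limma called 1919 probe sets, 1201 higher and 718 lower on LRD-5001, with 3053 with the arrays apart as a block and 2798 without them.

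In the averaged contrast 15 of 24 cytochrome P450 genes rose and 9 did not pass (16 adjusted over the list alone; adjusted p = 0.000106 with an estimated correlation). Of the conjugation genes, 14 of 18 rose (15 adjusted over the list alone), with Ugt2b35 (1.28, SE 0.11) and Sult1b1 (1.48, SE 0.20). Of the Nrf2 and glutathione genes, 13 of 24 rose and 1 fell (15 and 2 adjusted over the list alone). Of 15 genes of amino acid breakdown, 7 rose (10 adjusted over the list alone), and each of these 3 lists had adjusted p = 0.00145 with an estimated correlation. Of 22 lipogenesis genes, 15 fell (18 adjusted over the list alone), including the desaturase Scd1 (-1.11, SE 0.12; adjusted p = 0.00377 for the list with an estimated correlation). Of 20 cholesterol genes, 10 rose (12 adjusted over the list alone; adjusted p = 0.0112 with an estimated correlation). Of 16 bile acid genes, 7 rose (9 adjusted over the list alone), with the transporter Slco1a4 (2.18, SE 0.21) and Cyp7a1, the rate-limiting enzyme of bile acid synthesis (1.82, SE 0.31; adjusted p = 0.0446 for the list with an estimated correlation). In the arsenic handling list 5 of 16 genes rose (5 adjusted over the list alone), with Abcc3 (2.77, SE 0.16) and Gsto1, an omega-class glutathione transferase (0.72, SE 0.08), and the list median was 0.017 (adjusted p = 0.00767 with an estimated correlation).

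The acute phase, inflammatory signalling, Kupffer cell and neutrophil lists were lower on LRD-5001 in the averaged contrast. Their calls did not hold with an estimated correlation. Of 23 acute phase genes, 13 fell and 10 did not pass (19 fell adjusted over the list alone), for example the pentraxin Apcs (-1.39, SE 0.29; adjusted p = 0.0856 for the list with an estimated correlation). Of 22 inflammatory signalling genes 5 fell, among them Stat3 (-0.58, SE 0.10) and Il1r1 (-1.0, SE 0.19), with 5 adjusted over the list alone (adjusted p = 0.0511 with an estimated correlation). Among cell type markers, 4 of 13 Kupffer cell genes fell (7 adjusted over the list alone; Clec4f -0.40, SE 0.09; adjusted p = 0.214 with an estimated correlation), as did 2 of 10 neutrophil genes, S100a8 (-1.25, SE 0.32) and S100a9 (-1.30, SE 0.30), with 3 adjusted over the list alone (adjusted p = 0.214 with an estimated correlation). Of 10 pericentral genes 5 rose (7 adjusted over the list alone), and of 8 periportal genes 3 rose (4 adjusted over the list alone), each list with adjusted p = 0.0744 with an estimated correlation. Of 6 MHC class II genes, 3 rose (4 adjusted over the list alone; H2-Eb1 0.68, SE 0.18; adjusted p = 0.252 with an estimated correlation).

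The 4 diet contrasts share no arrays, and 40 probe sets were called with 1 sign in all of them, 34 higher and 6 lower on LRD-5001. Independent lists would share 5.6e-06 and 1.4e-06 probe sets. These lists are not independent, since all 4 contrasts use 1 spread per probe set from the 39 arrays. For 28 genes the representative probe set is among the 40. Genes with a shared probe set that was higher include Gsta2, Clec2h, Cyp26a1, Abcc3, Cyp2c54, Cyp2c55, Gstt2, the aldehyde oxidase Aox1, Ephx1, Ugdh, Cth, which makes cysteine, and Hmgcs1. Those with a lower one include Apoa4, Fabp5 and Apoc2. Of the 256 probe sets called in controls, 239 (93.4%) kept their sign at the other 3 exposure levels, where chance gives 12.5%. The shared count was 65 with the arrays apart as a block and 39 without them, 19 with all 59 arrays in 1 fit, and 11 with only the groups compared.

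**Figure D3:**
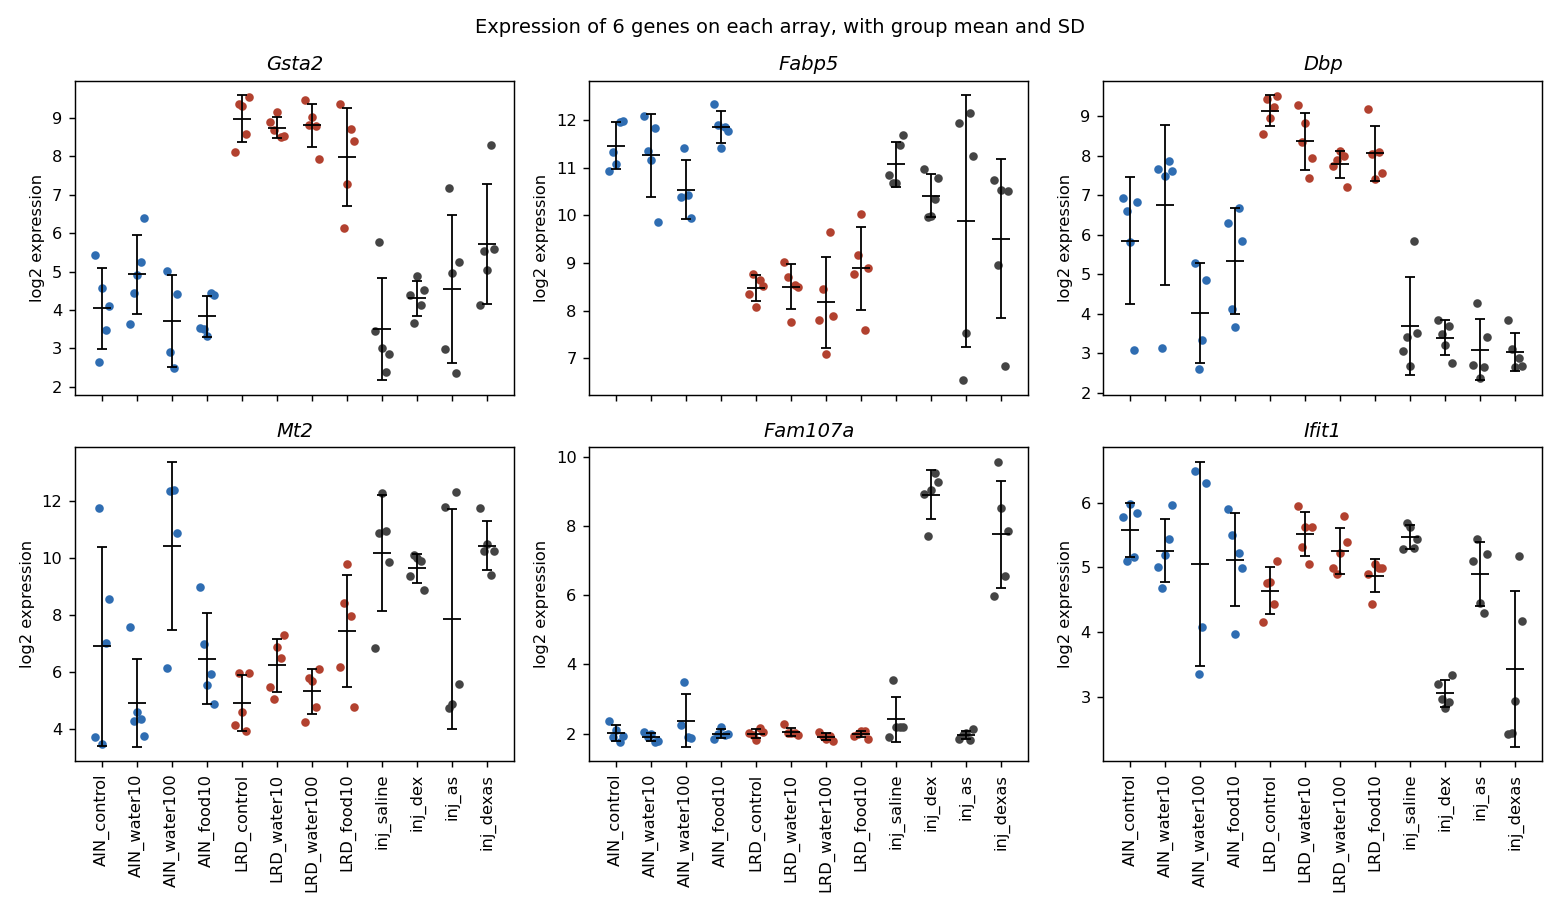
Log2 expression of single genes on each array by group, with group mean and SD. Gsta2 lies higher on LRD-5001 than on AIN-76A in controls (8.98 against 4.04), and Fam107a lies higher after dexamethasone than after saline (8.91 against 2.41).

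On AIN-76A, 10 ppb arsenite in water changed no single gene past the threshold. The genes with the smallest p were 4930504C09Rik (0.37, SE 0.08), Rasl11a (-0.41, SE 0.10), Hmgcll1 (0.36, SE 0.08), Nop56 (-0.59, SE 0.15) and Mfsd13b (0.32, SE 0.08), each with an adjusted p of 0.993. In this contrast limma called 0 probe sets, with 2178 at an unadjusted p under 0.05. The ER stress list, which holds the chaperones Hspa5 (-0.43, SE 0.17) and Hsp90b1 (-0.52, SE 0.20), was lower with 0 of 18 members passing, over all probe sets or adjusted over the list alone (list median -0.250, adjusted p = 0.000593; adjusted p = 0.547 with an estimated correlation). The lists called lower with the preset correlation also included cell cycle (19 genes, 0 passing, 0 adjusted over the list alone, with Ccnd1 at -0.79, SE 0.30, and Tyms at 0.22, SE 0.10; adjusted p = 0.0491; adjusted p = 0.646 with an estimated correlation).

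At 100 ppb in water on AIN-76A, Slc22a5, the carnitine transporter, rose from 4.92 ± 0.29 (SD, n = 5) in controls to 6.37 ± 0.82 (SD, n = 4), and Arhgap26 fell from 6.74 ± 0.59 (SD, n = 5) to 4.81 ± 1.04 (SD, n = 4), each with an adjusted p of 0.0485. The other two called probe sets were 1 for the iron transporter Slc11a2 (0.705, SE 0.101, adjusted p = 0.00176) and 1 for Hacd3, which takes part in making very long fatty acids (0.59, SE 0.11, adjusted p = 0.0485), both named after their values were seen and neither the brightest probe set of its gene. For each of the 4, the arrays of the groups did not overlap, which held for 1.69% of all probe sets. Slc22a5 lost its call without exposed replicates B (adjusted p = 0.203) and C (adjusted p = 0.0771) and without control replicates D, E and F (adjusted p = 0.0716, 0.121 and 0.153). Arhgap26 lost its call without exposed replicates B (adjusted p = 0.203) and C (adjusted p = 0.0916) and without control replicates B, D and F (adjusted p = 0.0764, 0.108 and 0.153).

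The kinase Pim3 (1.61, SE 0.33), the mitochondrial carnitine carrier Slc25a20 (0.78, SE 0.16) and the hydrolase Nudt19 (-0.76, SE 0.16) had the next smallest p at 100 ppb on AIN-76A and did not pass (adjusted p = 0.0926 each). Of 22 lipogenesis genes 0 passed over all probe sets, and 16 fell adjusted over the list alone, with Khk (-0.90, SE 0.19), Acly (-1.51, SE 0.37) and Thrsp (-1.96, SE 0.57; adjusted p = 1.35e-17 for the list; adjusted p = 0.0552 with an estimated correlation). Of 25 genes of fatty acid oxidation 0 passed, and 7 rose adjusted over the list alone, with Cyp4a14 (3.19, SE 0.72) and Eci2 (0.97, SE 0.21; adjusted p = 0.103 with an estimated correlation). Of 20 glucocorticoid targets 0 passed and 7 rose adjusted over the list alone, with Cdkn1a (1.97, SE 0.48) and Fkbp5 (1.70, SE 0.45). The list had adjusted p = 0.0761 with an estimated correlation. The acute phase, inflammatory signalling, Kupffer cell and neutrophil lists were also called, with the preset correlation only. The acute phase score was 12.2 and 12.1 in exposed replicates B and C, 9.53 in A and 11.2 in D, against 9.20 to 11.7 in controls.

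In that contrast limma called 4 probe sets, 3 higher and 1 lower, against 3996 at an unadjusted p under 0.05, and the count turned on single arrays. It was 572 without exposed replicate A, 89 without D, 9 without C and 0 without B, and 92, 1, 2 and 1 without control replicates C, D, E and F. It was 83 with the arrays apart as a block and 661 without them, 25 after quantile normalization, 2 with 1 probe set per gene, 2 with a variance trend, 1 with the replicate letter as a block, and 0 with all 59 arrays in 1 fit or with only the groups compared.

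With 10 ppb in food on AIN-76A, markers of stellate cells and fibroblasts were higher as a list, although no single gene passed over all probe sets. Of 12 markers 0 passed over all probe sets and 3 rose adjusted over the list alone, with the collagens Col3a1 (1.17, SE 0.32) and Col1a2 (0.97, SE 0.28) and the smooth muscle gene Tagln (0.67, SE 0.22). The list median was 0.483 (adjusted p = 9.07e-09; adjusted p = 0.0073 with an estimated correlation), and it was 0.223 without the 12 arrays apart. Fat markers were also higher as a list of 7 genes, 0 of them passing and 1 adjusted over the list alone, Lipe (0.56, SE 0.19), beside Fabp4 (1.36, SE 0.56) and Adipoq (0.94, SE 0.51; adjusted p = 0.00155; adjusted p = 0.131 with an estimated correlation). Without exposed replicate D the median of the fat list turned from 0.429 to -0.005. The cholesterol synthesis, lipogenesis, MHC class II and neutrophil lists were also called, with the preset correlation only. Here limma called 0 probe sets, with 1635 at an unadjusted p under 0.05, and the smallest p belonged to Zkscan6 (-0.38, SE 0.09), Col6a1 (0.60, SE 0.16), Tacr2 (-0.38, SE 0.10), Col3a1 and Arsi (-0.45, SE 0.12), none of which passed (adjusted p = 1).

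On LRD-5001 no gene passed for any arsenite exposure. Among named genes, the smallest p belonged to the phosphatase Dusp1 at 10 ppb in water (1.95, SE 0.41, adjusted p = 0.915), to Arntl at 100 ppb in water (1.17, SE 0.24, adjusted p = 0.82) and to Tef at 10 ppb in food (-0.77, SE 0.19, adjusted p = 1). The clock regulator Ciart had a difference of -0.71 (SE 0.18) at 100 ppb and of -0.68 (SE 0.18) with food, and the monooxygenase-related Moxd1 had one of 2.28 (SE 0.57) at 10 ppb in water and of 2.26 (SE 0.57) with food. In the clock list of 18 genes 0 passed at 100 ppb, and 1 rose and 4 fell adjusted over the list alone (adjusted p = 0.0155; adjusted p = 0.671 with an estimated correlation). With food, the acute phase list of 23 genes was higher with 0 passing and 0 adjusted over the list alone, including Lcn2 (4.63, SE 1.46) and Saa1 (2.56, SE 0.87). Its adjusted p was 8.82e-16, and 0.204 with an estimated correlation. Its score was 11.27 and 11.467 in food replicates C and D, against 9.355 to 9.938 in the other food arrays. The Kupffer cell list was also called with food, with the preset correlation only. T and NK cell markers had a median of 0.101 with food, with 0 of 12 passing and 1 adjusted over the list alone, Cd2 (0.34, SE 0.10; adjusted p = 0.0142; adjusted p = 0.169 with an estimated correlation). For water at 10 ppb, water at 100 ppb and food, limma called 0, 0 and 0 probe sets, with 1054, 1055 and 1031 at an unadjusted p under 0.05. Each of these is below the 2252 that chance gives. The spread per probe set is shared with the AIN-76A groups, so these tests are too strict where LRD-5001 groups vary less. How far this lowers the counts was not tested, so low counts are no evidence for an absence of effect. The count was 2 for water at 10 ppb without LRD-5001 control replicate C, 1 for food without exposed replicate B, and 2 for 100 ppb with only the groups compared.

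The effect of arsenite did not differ detectably between the diets for any single gene. The interactions of diet with water at 10 ppb, water at 100 ppb and food gave 0, 0 and 0 probe sets in limma, with 1866, 2757 and 1128 at an unadjusted p under 0.05. The interaction at 100 ppb gave 62 without AIN-76A exposed replicate A and 26 without the arrays apart. The stellate cell list, higher with food on AIN-76A, had an adjusted p of 0.000782 in the interaction with diet (median -0.541; adjusted p = 0.178 with an estimated correlation). Food against water at 10 ppb called 0 probe sets on AIN-76A and 0 on LRD-5001 in limma, with 2623 and 731 at an unadjusted p under 0.05. On AIN-76A that count was 5 with the arrays apart as a block and 1 without them, 2 with all 59 arrays in 1 fit and 1 without food replicate D, and on LRD-5001 it was 1 without water replicate C.

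Between 100 and 10 ppb in water on AIN-76A, metal-binding and stress genes were higher and lipogenic genes were lower at the higher dose. The male-biased list was lower too, but its call did not hold with an estimated correlation. The metallothionein Mt2 had a mean of 10.4 ± 2.94 (SD, n = 4) at 100 ppb and 4.92 ± 1.53 (SD, n = 5) at 10 ppb, and Mt1 of 11.3 ± 2.72 (SD, n = 4) and 6.38 ± 1.71 (SD, n = 5). High Mt2 values also occurred on AIN-76A without added arsenite. Mt2 ran from 3.48 to 11.8 in controls and from 6.87 to 12.3 after saline injection. The protease inhibitor A2m rose by 3.26 (SE 0.75). Inmt, an N-methyltransferase, fell from 10.9 ± 0.30 (SD, n = 5) to 7.20 ± 3.72 (SD, n = 4), the steroid dehydrogenase Hsd3b5 by 3.19 (SE 0.72), and the water channel Aqp8 by 3.08 (SE 0.54). For each of these 6 genes the arrays of the doses overlapped. All 6 lost their call without 100 ppb replicate B, with an adjusted p of 0.177 for Mt2, 0.179 for Mt1, 0.251 for A2m, 0.212 for Inmt, 0.205 for Hsd3b5 and 0.0714 for Aqp8. Without 100 ppb replicate C the adjusted p was 0.114 for Mt1 and Mt2, 0.172 for A2m, 0.142 for Inmt and 0.138 for Hsd3b5. Without 10 ppb replicate D it was 0.0608 for Mt2, 0.0605 for Mt1, 0.0704 for A2m, 0.0599 for Inmt and 0.0569 for Hsd3b5. Mt2, Mt1, A2m and Hsd3b5 also lost their call without 10 ppb replicates E and F, the highest adjusted p being 0.0743 for Mt1 without F, Mt1 without 100 ppb replicate D (adjusted p = 0.0515), and A2m without 10 ppb replicate A (adjusted p = 0.0515).

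Of 22 lipogenesis genes 8 fell at the higher dose and 14 did not pass (19 fell adjusted over the list alone), with Khk (-1.08, SE 0.19), Acss2 (-1.98, SE 0.37) and Acly (-1.99, SE 0.37). Of 23 heat shock and metal response genes 5 rose (13 adjusted over the list alone), with Cdkn1a (2.46, SE 0.48) and the heme oxygenase Hmox1 (1.58, SE 0.32), and of 20 glucocorticoid targets 4 rose (9 adjusted over the list alone), with Fkbp5 (2.35, SE 0.45). Of 18 ER stress genes 1 rose, Creld2 (1.96, SE 0.48), and 7 adjusted over the list alone. These 4 lists each had adjusted p = 0.0177 with an estimated correlation, while without 100 ppb replicate B the whole contrast called 10 probe sets. Of 22 inflammatory signalling genes 2 rose (9 adjusted over the list alone), Il1r1 (1.79, SE 0.40) and Il1rn (1.51, SE 0.37; adjusted p = 0.0212 for the list with an estimated correlation), and of 18 conjugation genes 1 fell (11 adjusted over the list alone), Ugt2b35 (-0.89, SE 0.22; adjusted p = 0.0484 with an estimated correlation). Of 12 male-biased genes 3 fell (9 adjusted over the list alone), with Serpina12 (-1.17, SE 0.26) beside Hsd3b5 (adjusted p = 0.0768 with an estimated correlation). Of 23 acute phase genes 1 rose, the metalloreductase Steap4 (2.11, SE 0.51), with 7 adjusted over the list alone (adjusted p = 0.136 with an estimated correlation), and 3 of 10 neutrophil markers rose (4 adjusted over the list alone), with S100a9 (2.75, SE 0.62; adjusted p = 0.106 with an estimated correlation).

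The dose contrast on AIN-76A called 321 probe sets, 136 higher and 185 lower, and limma called 0 on LRD-5001, with 829 there at an unadjusted p under 0.05. The difference of the dose effects between the diets was tested over the called probe sets only, and its value stands with the other observations. Without 100 ppb replicates A, B and C the count was 1278, 10 and 118, and without 10 ppb replicates A, D, E and F it was 205, 121, 158 and 195. It was 764 with the arrays apart as a block and 1109 without them, 482 after quantile normalization, 133 with the replicate letter as a block, 108 with all 59 arrays in 1 fit, and 0 with only the groups compared.

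Dexamethasone raised Fam107a, a glucocorticoid-responsive actin-binding gene, from 2.41 ± 0.65 (SD, n = 5) after saline to 8.91 ± 0.70 (SD, n = 5). The estrogen sulfotransferase Sult1e1 rose from 2.54 ± 0.36 to 7.37 ± 0.74 (SD, n = 5 each). Further rises were seen for the defensin Defb1 (3.36, SE 0.50), the ribonucleotide reductase subunit Rrm2 (3.26, SE 0.39), the lipid droplet protein Plin5 (3.08, SE 0.25), the receptor co-chaperone Fkbp5 (2.98, SE 0.55) and the sulfotransferase Sult1d1 (2.95, SE 0.38). The interferon-inducible GTPase Gbp6 fell from 5.17 ± 0.34 to 2.69 ± 0.22 (SD, n = 5 each). The interferon-induced Ifit1 fell by 2.41 (SE 0.39), the claudin Cldn2 by 2.35 (SE 0.34), the peroxisomal carnitine transferase Crot by 2.15 (SE 0.25) and the alcohol dehydrogenase Adh4 by 1.88 (SE 0.17). For each of these genes all 5 arrays of 1 group lay above all 5 of the other. The rule for named genes selects for this, and it held for 3.81% of all probe sets. Here limma called 782 probe sets, 443 higher and 339 lower. The count was 488 without saline replicate E, 473 without saline replicate F, 481 without dexamethasone replicate D, 448 without dexamethasone replicate F, and 1371 with all 59 arrays in 1 fit.

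Of 19 interferon response genes, 8 fell after dexamethasone and 11 did not pass (14 fell adjusted over the list alone), with Ifit3 (-1.76, SE 0.30) and Rtp4 (-1.80, SE 0.33; adjusted p = 1.16e-11 for the list; adjusted p = 0.0775 with an estimated correlation). Of 20 glucocorticoid targets 2 rose, Fkbp5 and Tdo2 (0.99, SE 0.21), and 6 rose and 1 fell adjusted over the list alone (adjusted p = 0.259 with an estimated correlation). Tdo2 lost its call without saline replicates C and E (adjusted p = 0.0509 and 0.0573) and without dexamethasone replicate F (adjusted p = 0.0536). Of 12 gluconeogenesis genes 3 rose and 1 fell (3 and 1 adjusted over the list alone; adjusted p = 0.292 with an estimated correlation). The glucose-6-phosphate transporter Slc37a4 (1.54, SE 0.19) and pyruvate carboxylase Pcx (1.03, SE 0.20) rose, while Pck1, the phosphoenolpyruvate carboxykinase of this pathway, fell by 1.68 (SE 0.39). Pck1 lost its call without saline replicates B, C, E and F (adjusted p = 0.0587, 0.0585, 0.0799 and 0.0759) and without dexamethasone replicates A, C and F (adjusted p = 0.0588, 0.0632 and 0.0979). Of 18 clock genes 4 rose (7 rose and 1 fell adjusted over the list alone; adjusted p = 0.0775 with an estimated correlation), with the deubiquitinase Usp2 (1.17, SE 0.27), which lost its call without saline replicates A, C and F (adjusted p = 0.0507, 0.0503 and 0.0867) and dexamethasone replicates A, D and E (adjusted p = 0.0704, 0.0789 and 0.0655). Kupffer cell markers were lower as a list, with 1 of 13 falling, Aif1 (-1.37, SE 0.33; 1 adjusted over the list alone), and adjusted p = 0.775 for the list with an estimated correlation. Aif1 lost its call without saline replicate F (adjusted p = 0.0759) and without dexamethasone replicates A, D, E and F (adjusted p = 0.0712, 0.0948, 0.0843 and 0.0878). The Kupffer cell score was 8.483 in saline replicate E, against 5.807 to 6.835 in the other saline arrays. The list kept its call with the preset correlation when any single array was left out.

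After arsenite injection alone no gene passed. The smallest p belonged to the centromere gene Cenpm (-0.66, SE 0.11, adjusted p = 0.497), the lipin Lpin2 (-1.09, SE 0.22), the growth factor binding protein Igfbp1 (-2.15, SE 0.47), Svs3a (0.34, SE 0.08) and Rdh16f2 (-0.76, SE 0.19), the last 4 with an adjusted p of 1. Glucocorticoid targets were lower as a list, with 0 of 20 passing and 1 falling adjusted over the list alone, Igfbp1 (list median -0.688, adjusted p = 6.18e-08; adjusted p = 0.0706 with an estimated correlation). Heat shock and metal response genes were higher as a list with 0 of 23 passing and 0 adjusted over the list alone, with Hspa1a (0.73, SE 0.30) and Hspb1 (0.83, SE 0.36; adjusted p = 0.00252; adjusted p = 0.746 with an estimated correlation). In this contrast limma called 0 probe sets, with 1414 at an unadjusted p under 0.05, and 1 without saline replicate B.

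Dexamethasone with arsenite raised Fam107a to 7.76 ± 1.56 (SD, n = 5) and Sult1e1 to 6.60 ± 1.43 (SD, n = 5), compared with saline, and lowered Gbp6 to 2.74 ± 0.37 (SD, n = 5). Fkbp5 rose by 2.92 (SE 0.55), Plin5 by 2.17 (SE 0.25) and Aass, which starts lysine breakdown, by 1.95 (SE 0.21). Osgin1, an oxidative stress induced gene, fell by 2.31 (SE 0.36) and Crot by 2.08 (SE 0.25). Of 20 cholesterol genes 5 fell and 15 did not pass (17 fell adjusted over the list alone), with the sterol enzymes Sc5d (-1.86, SE 0.19) and Nsdhl (-2.34, SE 0.47). The list had adjusted p = 2.05e-19, and 0.105 with an estimated correlation. It was also called after dexamethasone alone and after arsenite alone, with the preset correlation only. Its scores were 8.04 to 8.87 after saline, 6.87 to 8.45 after dexamethasone and 7.11 to 8.91 after arsenite. Nsdhl lost its call without saline replicate F (adjusted p = 0.0521) and without combined replicate C (adjusted p = 0.0591). Of 19 interferon response genes 3 fell (11 adjusted over the list alone), with Ifit1 (-2.03, SE 0.39; adjusted p = 0.105 for the list with an estimated correlation). Here limma called 417 probe sets, 226 higher and 191 lower. The count was 258 without saline replicate E, 224 without saline replicate F, 229 without combined replicate C, 916 with all 59 arrays in 1 fit and 221 with only the groups compared. It was 668 with the arrays apart as a block and 434 without them.

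On top of arsenite, dexamethasone raised Fam107a by 5.80 (SE 0.53), Fkbp5 by 3.97 (SE 0.55) and Sult1e1 by 3.74 (SE 0.53), and lowered Osgin1 (-2.35, SE 0.36), Gbp6 (-2.18, SE 0.22) and 1810008I18Rik (-2.10, SE 0.40). Of 20 glucocorticoid targets 5 rose and 15 did not pass (12 rose adjusted over the list alone), with Fkbp5, Cdkn1a (3.39, SE 0.58) and the leucine zipper gene Tsc22d3 (1.53, SE 0.34), and this list held its call (adjusted p = 3.85e-12; adjusted p = 0.0104 with an estimated correlation). Here limma called 397 probe sets, 261 higher and 136 lower. The count was 219 without combined replicate C, 846 with all 59 arrays in 1 fit, 119 with only the groups compared, 620 with the arrays apart as a block and 391 without them.

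The effect of dexamethasone without arsenite and with it rests on different arrays, so the signs and calls can be set side by side. The lists of calls are not independent, since both contrasts use the same spread per probe set from all injection arrays. The numbers expected of independent lists therefore cannot decide whether the sharing exceeds chance. Of the 443 and 261 probe sets called higher, 153 were shared (58.6% of the smaller list) where independent lists would share 2.57. Of the 339 and 136 called lower, 74.3% of the smaller list was shared, where independent lists would share 1.02 probe sets. Of the 782 called without arsenite, 768 (98.2%) had the same sign with it, and 0 were called in opposite directions. The interaction of dexamethasone and arsenite called 0 probe sets in limma, with 1560 at an unadjusted p under 0.05, and arsenite on top of dexamethasone called 0, with 1744. The latter was 16 with all 59 arrays in 1 fit and 2 without combined replicate C. In arsenite on top of dexamethasone the lipogenesis list was lower (median -0.652, adjusted p = 3.09e-09; adjusted p = 0.54 with an estimated correlation), with 0 of 22 passing and 0 adjusted over the list alone.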

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

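For the 12 arrays that lie apart, the tests of chance and of degraded RNA were chosen only after the pattern was seen, and the test of a distribution shift before its result was.

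On the first component of the deviations from the group means, 8 arrays lay far from the others of their group, the gap being 0.81 of the whole range for AIN-76A control replicate C, 0.81 for AIN-76A water 10 ppb replicate C, 0.828 for AIN-76A food replicate D, 0.773 for LRD-5001 water 10 ppb replicate F, 0.732 for LRD-5001 water 100 ppb replicate D, 0.839 for LRD-5001 food replicate C, 0.858 for dexamethasone replicate C and 0.823 for combined injection replicate E. The upper quartile was also far lower than in the rest of the group for AIN-76A control replicate C (0.719 of the range), LRD-5001 water 10 ppb replicate F (0.832), LRD-5001 water 100 ppb replicate D (0.713) and combined injection replicate E (0.734).

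These arrays belong to the 12 that lie apart, 1 in each group. A free draw of 12 arrays falls 1 to a group with probability 0.000174. The scores are centred within each group and the 12 arrays were cut from them, so this draw cannot decide about chance. The tables argue against degraded RNA, since the actin 3' minus 5' difference was lower on these arrays (mean -0.248, permutation p = 0.00095) where degradation raises it. They argue against a distribution shift that quantile normalization removes, since 12 of 12 groups kept the same lowest array after it. A processing step done on 1 sample of each group at a time is a candidate explanation that stays open, the labels give no such step, and no biological explanation was tested.

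Metallothionein Mt1 was far lower in AIN-76A water 100 ppb replicate A (7.26) than in the other arrays of its group (12.1 to 13.0), a gap of 0.841 of the range, and the score of the heat shock and metal response list was lower there too (5.41 against 6.71 to 6.86, a gap of 0.9). Mt2 was higher in AIN-76A water 10 ppb replicate A (7.60 against 3.75 to 4.62, a gap of 0.776). Fam107a was higher in saline replicate B (3.56 against 1.91 to 2.20, a gap of 0.824), still below the dexamethasone mean of 8.91. The bile acid list was lower in AIN-76A food replicate D (8.81 against 8.96 to 8.99, a gap of 0.828). Of 163 groups of values tested for such gaps, 17 passed where chance gives 8.2, about 1 in 20. Most of the 17 are component scores and upper quartiles of arrays that were cut out by that component. Among 76 groups of list scores and 39 of genes, only the gaps of this paragraph passed, no more than chance gives. Scores were tested only for lists whose call held with an estimated correlation. Among the untested scores were the fat score of AIN-76A food replicate D (4.933 against 2.865 to 2.996) and the neutrophil score of saline replicate E (5.451 against 2.797 to 3.019). Several untested scores of combined injection replicate E also lay far from its group. They were male-biased (7.21 against 8.83 to 10.3), cell cycle (4.52 against 3.18 to 3.48) and periportal (9.80 against 8.50 to 8.77). That array is part of every contrast with the combined injection.

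Gene lists moved differently between diets under arsenite, as tested by the interactions. With the preset correlation, 11 lists were called in the interaction with water at 10 ppb, 12 with water at 100 ppb and 13 with food, and 7 in the interaction of dexamethasone with arsenite. None of these list calls held with an estimated correlation.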

How the results depend on the processing

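The technical block, the fit without the 12 arrays apart and the settings of the gene lists other than the estimated correlation were chosen after seeing the data. Of 291 named gene values, 0 changed sign under any setting. Several settings leave the difference of group means as it is, and many named genes were chosen because their groups do not overlap. The count of sign changes therefore says little about stability. Of 258 called values 62 lost their call without some single array, 40 with all 59 arrays in 1 fit, 37 with only the groups compared, 33 without the 12 arrays apart, 30 with the replicate letter as a block, 6 after quantile normalization, 4 with a variance trend and 0 with the brighter probe sets alone. Of 197 list calls, 23 held with an estimated correlation, 88 were lost without some single array, 53 without the 12 arrays apart and 32 with all 59 arrays in 1 fit. Counts of calls changed by more than 1.5 times as follows, and apart from fewer arrays or genes the cause was not tested.

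With 1 probe set per gene, 100 ppb in water on AIN-76A gave 2. With all 59 arrays in 1 fit, diet in controls gave 157, 100 ppb in water on AIN-76A 0, food against water on AIN-76A 2, 100 against 10 ppb 108, shared diet calls 19, dexamethasone 1371, dexamethasone with arsenite 916, arsenite on top of dexamethasone 16 and dexamethasone on top of arsenite 846. After quantile normalization, 100 ppb in water on AIN-76A gave 25 and 100 against 10 ppb 482, and with a variance trend the former gave 2. With only the groups compared, diet in controls gave 165, 100 ppb in water 0 on AIN-76A and 2 on LRD-5001, 100 against 10 ppb 0, dexamethasone with arsenite 221, dexamethasone on top of arsenite 119 and shared diet calls 11. With the technical block, diet in controls gave 434, diet averaged 3053, 100 ppb in water on AIN-76A 83, food against water on AIN-76A 5, 100 against 10 ppb 764, shared diet calls 65, dexamethasone with arsenite 668 and dexamethasone on top of arsenite 620. Without the 12 arrays apart, 100 ppb in water on AIN-76A gave 661, its interaction with diet 26, food against water on AIN-76A 1 and 100 against 10 ppb 1109.

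Leaving out single arrays gave ranges of 165 to 341 for diet in controls, 0 to 572 for 100 ppb in water on AIN-76A, 0 to 62 for its interaction with diet, 0 to 1 for food against water on AIN-76A and on LRD-5001, 10 to 1278 for 100 against 10 ppb on AIN-76A, 0 to 2 for 10 ppb in water and 0 to 1 for food on LRD-5001, 448 to 823 for dexamethasone, 0 to 1 for arsenite injection, 224 to 561 for dexamethasone with arsenite, 0 to 2 for arsenite on top of dexamethasone and 219 to 487 for dexamethasone on top of arsenite. The median of the fat list for food on AIN-76A ranged from -0.005, without food replicate D, to 0.619, without food replicate E. The median of the cholesterol list between 100 and 10 ppb on AIN-76A turned from -0.098 to 0.032 without the 12 arrays apart and to 0.021 without 100 ppb replicate D, the lowest being -0.334 without replicate C.

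With the replicate letter as a replicate block, 100 ppb in water on AIN-76A gave 1 and 100 against 10 ppb gave 133. Of 136 same-letter pairs of arrays, 43 had a correlation of deviations over 0.1 (median -0.0315), and 16 of 59 arrays matched best with their own letter, so the letters were not taken as pairs.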

Other observations

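The tests of other splits of the samples and of circadian phase were chosen only after the results were seen, and part of the criterion of the dose test was edited after its first result; the tests of the acute phase state and of the clock as the whole cause were chosen before their results were.

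Several gene lists were called in no contrast. The smallest adjusted p of any contrast was 0.0676 for female-biased genes, 0.245 for hepatocyte genes, 0.0634 for B cells, 0.0559 for endothelium, 0.418 for bile duct cells, 0.458 for red cells and 0.245 for pancreas.

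The dose difference on AIN-76A, which includes metallothionein and lipogenic genes and the acute phase gene Steap4, was set against 2 explanations. In the saline and arsenite injection arrays, none of them in the contrast, 90.9% of 320 called probe sets outside the acute phase list had a within-group slope on the acute phase score with the sign of the dose difference (permutation p = 0.0552, one-sided, 10000 permutations). An acute phase state of single mice may therefore underlie part of these calls, and arsenite as the cause of that state stays open. High acute phase scores also occurred on AIN-76A without added arsenite. Scores ran from 9.20 to 11.7 in controls and from 9.97 to 11.7 after saline, against 9.53 to 12.2 at 100 ppb in water. For these called probe sets only, an equal dose effect on both diets is argued against, since 35.8% had the same sign on LRD-5001. The exact permutation p of 0.972 (one-sided, 252 splits) tests only for an excess of equal signs. A dose effect on other probe sets was not addressed, and selection enlarges the difference on AIN-76A. The mean difference in the called direction was 1.24 (SE 0.374) on AIN-76A, where the probe sets were selected, and -0.08 (SE 0.026) on LRD-5001.

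Clock genes were set against a difference in circadian phase between the diets. The 10 output genes, such as Dbp and Tef, and the 5 genes of the opposite arm, such as Arntl and Nfil3, moved apart, with an arm score difference of 1.224 (permutation p = 1e-05, the smallest these permutations can give). The arms hold genes whose opposite changes were seen before the test was chosen, so this p partly restates them. A phase difference at collection may explain this, whether set by diet or by collection time, which is not given in the sources used here. With the clock score as a covariate, 105 probe sets were called in the averaged contrast, against 1919 without it. Of the 40 probe sets called in all 4 diet contrasts, 32 passed. Gsta2 (3.08), Abcc3 (2.36) and Apoa4 (-2.80) passed, and Dbp (0.04) and Arntl (-0.44) did not. The 40 were chosen for their diet difference and the score is confounded with diet, so this cannot decide whether the clock is the whole cause.

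For each result, 100 splits of the samples, the real one included, were compared. Chance can be excluded for diet in controls (256 calls, 27 at most in another split), diet averaged over exposures (1919, 0 at most), diet calls shared by the 4 levels (40, 0 at most), dexamethasone (782, 2 at most), dexamethasone with arsenite (417, 31 at most) and dexamethasone on top of arsenite (397, 97 at most), where only 1 split, the real one, gave a count as large. Chance cannot be excluded for 100 ppb in water on AIN-76A, where 20 splits gave a count as large as 4 and the highest other was 942, nor for 100 against 10 ppb on AIN-76A, where 6 splits gave one as large as 321 and the highest other was 1721. Some splits call several times the real count, and what sets their arrays apart was not tested.

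Where the real count was 0 in limma, every split gives a count as large by definition, so the splits cannot decide about chance there. The counts at an unadjusted p under 0.05 stand with each contrast. The highest other count was 48 for 10 ppb in water and 5 for food on AIN-76A, and 1, 1 and 3 for 10 ppb in water, 100 ppb in water and food on LRD-5001. It was 1, 221 and 3 for the interactions of diet with 10 ppb in water, 100 ppb in water and food. What the split with 221 calls separates was not tested. It was 1 and 0 for food against water on AIN-76A and LRD-5001, 0 for 100 against 10 ppb on LRD-5001, 52 for arsenite injection, 6 for arsenite on top of dexamethasone and 2 for the interaction of dexamethasone with arsenite.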
